A study of Mus musculus with 6 samples.

How the data were processed

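The data are 6 microarrays of total RNA from mouse primary cortical neuron cultures, 3 infected with a lentivirus carrying a control short hairpin RNA (shRNA) and 3 with a lentivirus carrying an shRNA against Cugbp1, the older name of Celf1. The deposited values are log2 RMA expression values with 1 value per exon probe set and array, computed in Affymetrix Expression Console per the labels and the submitters' processing notes. RMA corrects background, normalizes arrays to a shared distribution and summarises the probes of a probe set, so differences in total signal between arrays are removed before any comparison. The software version and which arrays were normalized together are not given in the sources used here. The processing notes name the mm9 genome build, and positions of probe sets were not used here, so no exon is placed within its gene.

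The table held 1195555 probe sets. At the 5th, 25th, 50th, 75th and 95th percentiles the 6 columns differed by at most 0.0653 on the log2 scale, under the limit of 0.1 fixed before the data were examined, so the deposited values were used as they were. Array medians lay between 5.74 and 5.78. The platform's probe annotation gave a single gene symbol to 317245 probe sets and several to 6323, and it did not list 871987. Of 22274 symbols, 17991 were current in the RefSeq gene table of assembly GRCm38.p6, 4220 were updated through its synonyms and 63 were kept as given, which left 22076 genes. That table served for names only.

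A probe set was kept where its mean over the 6 arrays was at least the median of all probe sets, 5.73 on the log2 scale, a rule blind to group. This kept 597778 probe sets. A gene with at least 3 kept probe sets that belonged to it alone received 1 value per array by Tukey median polish, with a median of 12 probe sets per gene. The 16532 genes so measured were tested. Another 3432 genes had 1 or 2 such probe sets kept and 2112 had none, and these were not tested.

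Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), as Cugbp1 shRNA minus control over all 6 arrays with no further term. P values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 counted as a call. The same model was run on each kept probe set. Exon usage was tested with limma's diffSplice on 244785 probe sets, each against the rest of its gene, with a Simes test per gene. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and fry beside it. Tables were read with data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.

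The groups, the main model, the 23 gene lists, the rule for naming genes and 19 of the 28 alternative settings were fixed before the data were examined. The lists covered the CELF family, other splicing regulators, amyotrophic lateral sclerosis (ALS) and frontotemporal lobar degeneration (FTLD) genes, pan-neuronal, glutamatergic and GABAergic markers, voltage-gated channels, axon guidance and adhesion, astrocyte, oligodendrocyte lineage, microglia, endothelial and mural cell, and fibroblast and meninges markers. They also covered proliferation, neural progenitors, interferon response, inflammatory cytokines, immediate early genes, the unfolded protein and integrated stress response, p53 targets, cholesterol biosynthesis, oxidative phosphorylation and transcripts reported as regulated by CELF1. The genes named are the CELF genes, the 12 called genes with the largest rise and the 12 with the largest fall among those whose groups did not overlap on the arrays, up to 4 members of each list with the smallest p, and the 10 probe sets with the smallest diffSplice p.

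Replicates 2 and 3 carry their number in the title. The array of each group without a number was taken as replicate 1, by exclusion. Deviations of gene values from the group means correlated between same-numbered arrays of the 2 groups at 0.76, 0.50 and 0.71, across genes, which are not independent replicates. A fit with the replicate number as a block, an alternative also fixed before the data were examined, was run beside the main one. The model without the block stayed the main one because it had been fixed as such in advance. The other alternatives were a random block, a block for the label form, quantile normalization, median centring, no filter and a filter at the 75th percentile, eBayes with trend and robust variances, array weights, an adjusted p under 0.10, means in place of median polish, 1 probe set per gene, an estimated list correlation, and leaving out each array in turn. The 9 settings added after seeing the data were the 3 pairs of replicate numbers alone, the same 3 pairs with a replicate block, and 3 forms of a splicing index, in which each probe set minus its gene value is tested with its own variance.

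The tests were tried on simulated data for the comparison of Cugbp1 shRNA with control over 16532 genes, with 200 genes and 200 single probe sets changed. A simulation with independent noise on each array recovered 11.8%, 63.6% and 95.5% of genes changed by 0.5, 1 and 2 on the log2 scale, with 3.42% of gene calls false. There diffSplice recovered 41% and 96% of probe sets changed by 1 and 2, and 88.7% of its 1212 calls were false. After that result was seen, another simulation was made in which same-numbered arrays shared part of their noise. The variances behind the noise were also moderated, across genes and across probe sets. It recovered 13.2%, 92.4% and 98.5% of genes with no false gene call among 135, and 15.6% of 160 diffSplice calls were false. Pairing and moderation changed together, so the lower share of false diffSplice calls cannot be credited to either. Moderated probe set variances lie closer to the 1 variance per gene that diffSplice uses, so this share may be too low for these arrays. The independent simulation used unmoderated variances, whose spread includes estimation error, so its share of 88.7% may be too high. It gave 1212 diffSplice calls where the 6 arrays themselves gave 201. Which simulation is closer to these arrays is not settled. With the replicate block, the paired simulation gave 5.83% false gene calls and 71.6% false diffSplice calls. There the block recovered 86.8%, 100% and 100% of genes changed by 0.5, 1 and 2. In the independent simulation it recovered 0%, 30.3% and 86.4%, with 1.28% false gene calls and 88.4% false diffSplice calls. Without the block the splicing index had 3.23% false calls in the independent simulation and none in the paired one, but it recovered 0% and 10% of probe sets changed by 1 and 60% and 72% of those changed by 2. With the block it recovered none in the independent simulation, and 47% and 98% in the paired one with 5.84% false calls. The labels do not say whether arrays of a group came from separate cultures, so p values measure the spread between these arrays, which may be partly technical, and their number limits the precision.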

Results

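The experiment asked how lowering Cugbp1 changes gene expression in cultured mouse neurons. Celf1, the current name of Cugbp1, encodes an RNA-binding protein that acts in alternative splicing, mRNA decay and translation. Cortical cells were taken from C57BL/6 embryos at embryonic day 15, freed of meninges, and treated early in culture with AraC, which blocks DNA synthesis and removes dividing cells. Lentivirus was applied for 4 hours on day 5, and RNA was collected on day 11 after 6 further days. For each array 100 ng of total RNA was labelled, with 3 arrays per group and 1 value per exon probe set. Other effects of the Cugbp1 shRNA cannot be told apart here from those of lowering Celf1, and they were not tested. The labels are not uniform, since the treatment text of replicates 2 and 3 of both groups names an shRNA against Tdp-43, and the design text of the series speaks of motor neurons where its title and samples speak of cortical neurons.

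Celf1 fell in the cultures given the Cugbp1 shRNA. Its gene value was 10.80 ± 0.05 (SD, n = 3) in control arrays and 9.44 ± 0.14 (SD, n = 3) in knockdown arrays, a log2 fold change of -1.36 with a standard error of 0.10 (limma, adjusted p = 0.0124). This left 39.1% of the control level, with a 95% confidence interval of 33.3% to 45.9%. The change was -1.25, -1.39 and -1.43 in replicates 1, 2 and 3. Of the 27 Celf1 probe sets kept, 24 had a lower mean, and 22 were lower when adjusted over these probe sets alone, while 0 passed over all probe sets (smallest adjusted p = 0.417, limma).

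The other CELF genes did not pass. Celf2 had a log2 change of 0.20 (adjusted p = 0.482), Celf3 of -0.14 (adjusted p = 0.806) and Celf4 of -0.08 (adjusted p = 0.730). Celf5 was at -0.27 (adjusted p = 0.179) and Celf6 at -0.30 (adjusted p = 0.271), and both passed with the replicate block (adjusted p = 0.0274 and 0.0221). Tardbp, which encodes TDP-43, differed by -0.035 with a standard error of 0.16 (adjusted p = 0.961), and did not pass. In replicates 2 and 3 alone, a subset chosen after seeing the data, Celf1 was at -1.40 (limma, adjusted p = 0.0301) and Tardbp at -0.042 (adjusted p = 0.901). The arrays whose text names Tdp-43 thus showed a called fall of Celf1 and none of Tardbp. Without single arrays Celf1 kept its direction, at -1.43 to -1.32, but passed only without control replicate 1 (adjusted p = 0.0307) and reached 0.0540 to 0.141 in the other 5 cases.

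**Figure D1:**
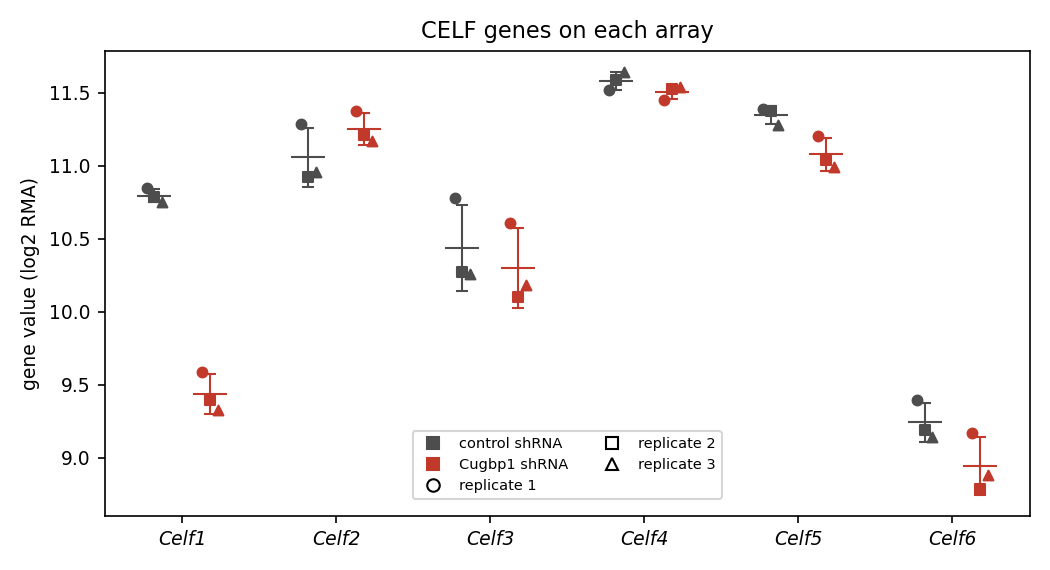
Gene values (log2 RMA) of the 6 CELF genes on each array, with control shRNA in grey, Cugbp1 shRNA in red, a symbol per replicate number, and bars at the mean and SD of 3 arrays. Celf1 lies at 10.80 in control and 9.44 in knockdown arrays with no overlap, and the changes of Celf2 to Celf6 did not pass the test.

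Across the transcriptome more genes fell than rose. Tspan2, a tetraspanin, fell most, by 2.06 on the log2 scale (standard error 0.15, adjusted p = 0.0124), followed by Rap2c, a Ras-family GTPase, which fell by 1.82, and Fgfbp3, a binding protein of fibroblast growth factors, which fell by 1.56. Zmat3, an RNA-binding zinc finger protein and p53 target, rose by 1.32 (standard error 0.13, adjusted p = 0.0124). Dcp2, the catalytic subunit of the mRNA decapping complex, rose by 1.31, as did Smarcd1, a subunit of SWI/SNF chromatin remodelling complexes. Of 16532 genes tested with limma, 181 were higher and 471 lower at an adjusted p under 0.05, and 3106 had an unadjusted p under 0.05.

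Txndc5, a protein disulfide isomerase of the endoplasmic reticulum, fell by 1.22 (adjusted p = 0.0124), Fabp3, a fatty acid binding protein, by 1.18 (adjusted p = 0.0168), and Echs1, an enzyme of mitochondrial fatty acid oxidation, by 1.17 (adjusted p = 0.0202). Cbln4, a secreted synaptic organizer, fell by 1.16 (adjusted p = 0.0175). The guanine nucleotide exchange factor Mcf2 fell by 1.25, the SET domain protein Smyd5 by 1.24 and the zinc finger protein St18 by 1.22. The unnamed transcript 5730455P16Rik fell by 1.25 (adjusted p = 0.0174). Fgfbp3 was measured by 3 probe sets only.

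Among the rises, Tnfrsf10b, a death receptor for TRAIL, rose by 1.23 (adjusted p = 0.0233), and Frzb, a secreted Wnt antagonist, by 1.17 (adjusted p = 0.0157). Ephx1, the microsomal epoxide hydrolase, rose by 1.16 (adjusted p = 0.0174) and the sialyltransferase St6gal1 by 1.08 (adjusted p = 0.0124). Rsph4a, a radial spoke protein of motile cilia, rose by 1.10 (adjusted p = 0.0380), and Cfap300, a cilia and flagella associated protein, by 1.06 (adjusted p = 0.0308). Erich6 rose by 1.04 and D8Ertd738e by 1.22. The largest rise, a 3.04-fold one of the histone gene H4c12, Hist1h4k in the probe annotation (standard error 0.27 on the log2 scale, adjusted p = 0.0292), is uncertain because histone H4 genes are near-identical copies that array probes may not separate.

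Most called changes were moderate, with a median absolute log2 change of 0.63. At least a 2-fold change was seen for 16 called genes that rose and 36 that fell. The median log2 change of all genes was -0.015. A fit with the replicate block called 3834 genes, 1544 higher and 2290 lower, which included all 652 in the same direction. Leaving out single arrays gave 271 calls without control replicate 1, 1 without Cugbp1 shRNA replicate 1, and 0 without any of the other 4 arrays.

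**Figure D2:**
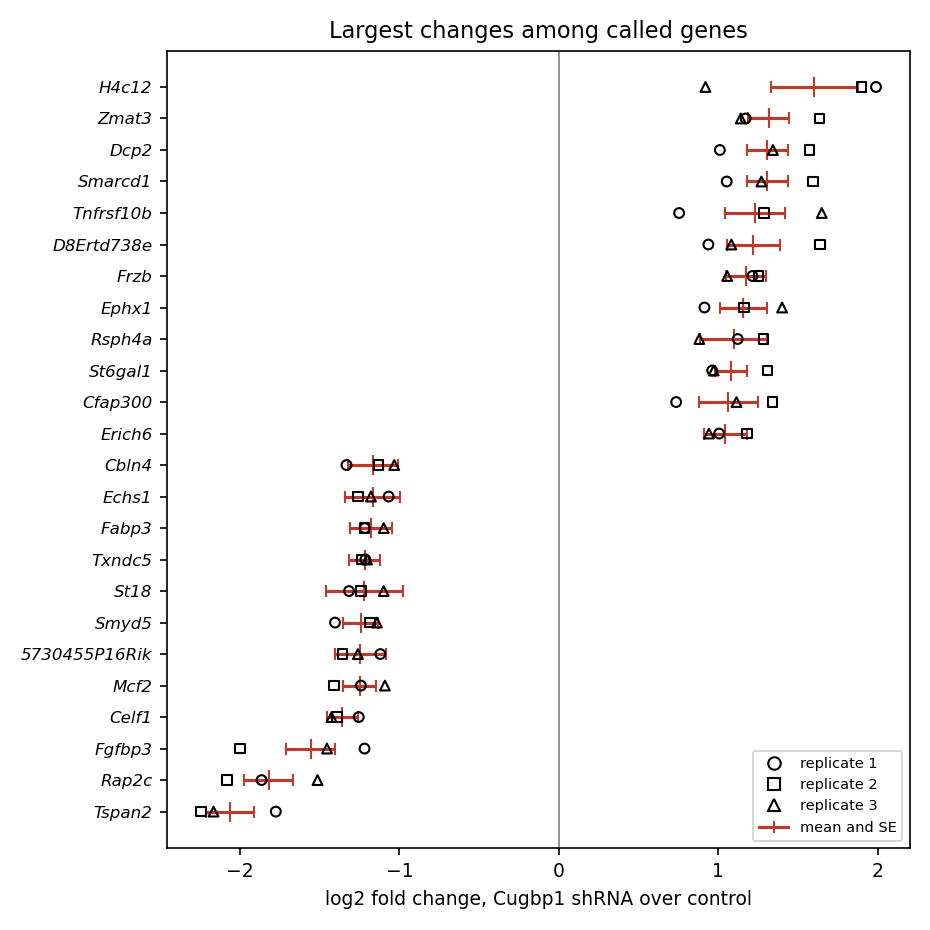
Log2 fold change of Cugbp1 shRNA over control for the 12 called genes with the largest rise and the 12 with the largest fall, with a symbol per replicate number and a red bar at the mean and standard error. In each of these genes all 3 replicates moved in the same direction, which their choice by groups without overlap required. The changes ran from Tspan2 at -2.06 to Zmat3 at 1.32 and, beyond it, H4c12, which rose 3.04-fold.

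Immediate early, proliferation and oxidative phosphorylation genes had mostly higher values, though few single genes passed. As background for all list counts, limma called 652 of all 16532 genes, and 3834 with the replicate block. An unadjusted p under 0.05 was reached by 3106. Of 24 immediate early genes, 19 had a higher mean and 2 rose: Npas4, a transcription factor induced by neuronal activity, by 1.04 (adjusted p = 0.0253), and Dusp6, a phosphatase of ERK kinases, by 0.59 (adjusted p = 0.0371). Fos, at 0.72 (adjusted p = 0.0751), and Fosb, at 0.71 (adjusted p = 0.0806), did not pass without the replicate block and passed with it. Adjusted over the list alone 4 rose, and with the replicate block 13. The list's median was 0.34 (camera adjusted p = 6.33e-05, and adjusted p = 0.812 with an estimated correlation), and it was 0.16 without control replicate 1 and 0.22 without Cugbp1 shRNA replicate 3.

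Of 18 proliferation genes, 17 had a higher mean and 0 passed in limma, over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05 and a median of 0.23, which was 0.086 without Cugbp1 shRNA replicate 2. The smallest p belonged to Bub1b, a spindle checkpoint kinase, at 0.43 (adjusted p = 0.0813), and Ccnb2, a mitotic cyclin, at 0.41 (adjusted p = 0.0938). The replicate block gave 8 that rose, these 2 included. Camera gave an adjusted p = 0.000311, and adjusted p = 0.878 with an estimated correlation. Of 23 oxidative phosphorylation genes, 22 had a higher mean and 0 passed in either way in limma, with 5 at an unadjusted p under 0.05, a median of 0.17 and with Atp5o, an ATP synthase subunit, at 0.50 (adjusted p = 0.0817). The replicate block gave 5 that rose, Atp5o included, and camera gave an adjusted p = 6.33e-05 (adjusted p = 0.732 with an estimated correlation).

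Cholesterol biosynthesis genes had mostly lower values. Of 19 such genes, 16 had a lower mean and 2 fell: Dhcr7, the enzyme of the last step to cholesterol, by 1.09 (standard error 0.12, adjusted p = 0.0157), and Nsdhl, a sterol dehydrogenase, by 0.82 (adjusted p = 0.0240). Lanosterol synthase, Lss, was at -0.50 (adjusted p = 0.0728) and Hsd17b7 at -0.44 (adjusted p = 0.0906). Adjusted over the list alone 6 fell, and with the replicate block 9 fell, Lss and Hsd17b7 included, and 1 rose. Camera gave an adjusted p = 0.000713, and adjusted p = 0.878 with an estimated correlation. The list's median was -0.17, and -0.11 without Cugbp1 shRNA replicate 2.

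Of 17 p53 targets 2 rose, Zmat3 and Tnfrsf10b, both also when adjusted over the list alone, and with the replicate block 5 rose and 1 fell. Btg2, an antiproliferative gene also counted among the immediate early genes, was at 0.36 (adjusted p = 0.121), and Sesn1, a stress-induced regulator, at -0.27 (adjusted p = 0.154), and both passed with the block. Camera gave an adjusted p = 0.0103, and adjusted p = 0.812 with an estimated correlation. The unfolded protein and integrated stress response list, with Sdf2l1 at 0.46 (adjusted p = 0.0736) and Atf5 at 0.45 (adjusted p = 0.0808) among 19 genes of which 0 passed in limma (4 at an unadjusted p under 0.05), reached a camera adjusted p of 0.0577 and passed with the replicate block (0.0379), by which 4 of its genes rose, Sdf2l1 and Atf5 included, and 1 fell. It also passed without control replicate 3 (adjusted p = 0.000560), but had an adjusted p = 0.878 over all 6 arrays with an estimated correlation. The immediate early, proliferation, oxidative phosphorylation, cholesterol and p53 lists were the 5 past the camera threshold among 23. None of the 23 passed with an estimated correlation, and fry, which tests whether a list's own genes moved on balance in 1 direction, passed for none (smallest adjusted p = 0.0997), while its test of change in either direction passed for 13. Without Cugbp1 shRNA replicate 1, 8 lists passed the camera threshold at the preset correlation. Those of the CELF family, which holds the shRNA target Celf1, neural progenitors and the stress response came in addition.

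Called neuronal markers went in both directions. Of 20 pan-neuronal genes, Ina, the neurofilament protein internexin, fell by 0.60 (adjusted p = 0.0198) and Stx1a, a syntaxin of synaptic vesicle release, rose by 0.88 (adjusted p = 0.0373), while Dcx, a microtubule protein of migrating neurons, was at -0.45 (adjusted p = 0.0892). Of 21 glutamatergic genes 0 passed in limma (6 at an unadjusted p under 0.05), with Camk2a at -0.58 (adjusted p = 0.0735). Of 16 GABAergic genes, Gad2, a glutamate decarboxylase that makes GABA, rose by 0.77 (standard error 0.11), with Gad1 at 0.46 (adjusted p = 0.0712) and the interneuron factor Lhx6 at -0.30 (adjusted p = 0.183). This list's median was -0.037 and its mean 0.039, so it has no settled direction. Dcx, Camk2a, Gad1 and Lhx6 passed with the replicate block (adjusted p = 0.00503, 0.00537, 0.00824 and 0.0235). Among 22 voltage-gated channels, Hcn2, a pacemaker channel, fell by 0.59 (adjusted p = 0.0342), and among 30 guidance and adhesion genes Epha4, an ephrin receptor, rose by 0.66 (adjusted p = 0.0238). Adjusted over the list alone, 1 pan-neuronal gene rose and 3 fell, 2 GABAergic genes rose, 1 channel gene rose and 1 fell, 1 guidance gene rose and 2 fell, and no glutamatergic gene passed. By the replicate block 2 pan-neuronal genes rose and 3 fell, 1 glutamatergic gene rose and 6 fell, 3 GABAergic genes rose and 3 fell, 4 channel genes rose and 3 fell, and 2 guidance genes rose and 6 fell. For these lists the background is 3834 of all 16532 genes called by that fit. These lists had camera adjusted p values of 0.401 (pan-neuronal), 0.241 (glutamatergic), 0.557 (GABAergic), 0.570 (channels) and 0.713 (guidance).

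Of 27 other splicing regulators, Ptbp3 fell by 0.65 (adjusted p = 0.0405) and Rbfox1, a neuronal splicing factor, fell by 0.39 (adjusted p = 0.0434), while Mbnl1, often described as an antagonist of CELF proteins, was at 0.36 (adjusted p = 0.147, and 0.0107 with the replicate block). Of 20 ALS and FTLD genes, C9orf72 rose by 0.92 (adjusted p = 0.0299). Dctn1, a subunit of the dynein cofactor dynactin, fell by 0.53 (adjusted p = 0.0299), Fig4, a phosphoinositide phosphatase, by 0.53 (adjusted p = 0.0330) and Optn, an autophagy receptor, by 0.63 (adjusted p = 0.0428). Of 26 transcripts reported as regulated by CELF1, the tight junction gene Ocln fell by 0.88 (adjusted p = 0.0174) and 25 did not pass. Adjusted over the list alone, 2 splicing regulators fell, 2 ALS and FTLD genes rose and 3 fell, 1 reported transcript fell, and Celf1 alone fell in the CELF family. By the replicate block 2 splicing regulators rose and 2 fell, 6 ALS and FTLD genes rose and 4 fell, 4 reported transcripts rose and 2 fell, and 3 CELF genes fell. That fit called 3834 of all 16532 genes, and these counts were not tested against that share. Camera adjusted p values were 0.713, 0.557, 0.545 and, for the CELF family, 0.0638, which passed without Cugbp1 shRNA replicate 1 (adjusted p = 0.0142) or control replicate 2 (adjusted p = 0.0311) at the preset correlation. Over all 6 arrays the CELF list had an adjusted p = 0.878 with an estimated correlation. It holds Celf1, the target of the shRNA, so its fall is partly built in, and it was not tested without Celf1.

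Few markers of other cell types passed without the replicate block. Of 18 astrocyte, 14 oligodendrocyte lineage and 16 microglia markers 0 passed in limma over all genes or adjusted over the list alone, and 3, 0 and 0 had an unadjusted p under 0.05. By the replicate block 1 astrocyte marker, Acsbg1, rose by 0.36 and 3 fell, among them Ntsr2 by 0.87 and Mlc1 by 0.53, and the microglia marker C1qa fell by 0.23. The mural cell receptor Pdgfrb fell by 0.80 (adjusted p = 0.0414) among 13 endothelial and mural cell markers, and Thbs1, a matrix glycoprotein, fell by 0.72 (adjusted p = 0.0443) among 16 fibroblast and meninges markers. Of 15 progenitor genes Hopx rose by 0.72 (adjusted p = 0.0266), with a camera adjusted p of 0.0638 for the list. Ddx58, an RNA sensor, rose by 0.87 (adjusted p = 0.0428) among 17 interferon response genes. Of 18 inflammatory genes 0 passed in limma (1 at an unadjusted p under 0.05), with the chemokine Cxcl12 at -0.93 (adjusted p = 0.0555, and 0.00194 with the replicate block), and this list's median of 0.010 and mean of -0.045 differed in sign. Adjusted over the list alone, 1 endothelial and mural, 1 fibroblast and meninges and 1 inflammatory gene fell, and 2 progenitor and 1 interferon response genes rose. By the replicate block 2 progenitor and 2 interferon response genes rose and 1 of each fell, 2 inflammatory genes fell, and 1 fell among the endothelial and mural and 1 among the fibroblast and meninges markers. Among all 16532 genes that fit called 3834. Camera adjusted p values of the astrocyte, oligodendrocyte lineage, microglia, endothelial and mural, fibroblast, interferon and inflammatory lists ran from 0.514 to 0.912. The oligodendrocyte lineage list, at 0.514, passed without control replicate 1 (median 0.19, adjusted p = 0.0182), and the progenitor list passed without Cugbp1 shRNA replicate 1 (adjusted p = 0.0241), both at the preset correlation. Over all 6 arrays they had an adjusted p = 0.942 and 0.878 with an estimated correlation.

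**Figure D3:**
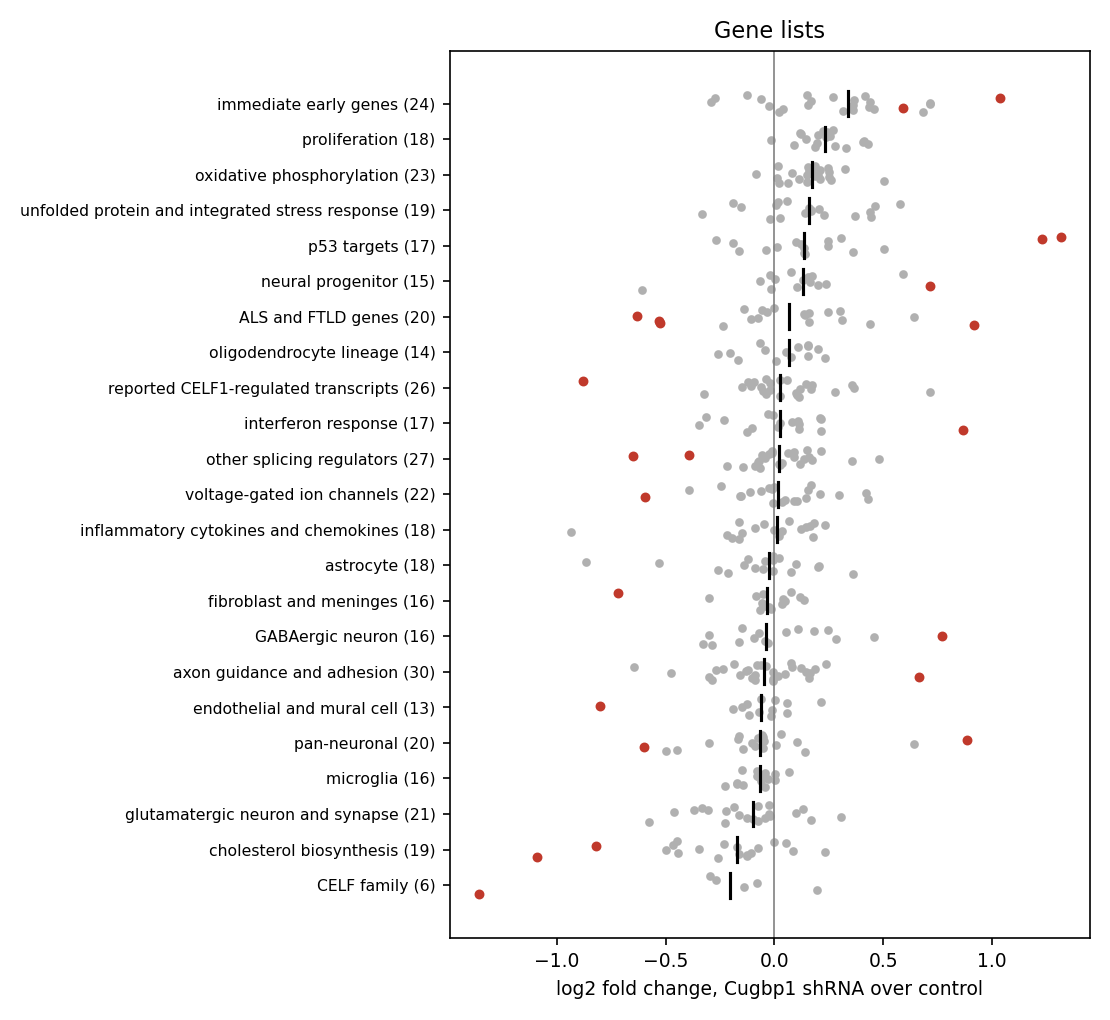
Log2 fold change of Cugbp1 shRNA over control for the measured members of the 23 gene lists, with the number measured in brackets, members called by limma in red, the others in grey and the list median as a black line. The medians run from -0.20 for the CELF family, which holds Celf1, to 0.34 for the immediate early genes, and most members of the shifted lists were not called.

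Exon usage, the relative level of a probe set within its gene, was compared because CELF1 regulates splicing. By diffSplice relative falls among the 10 probe sets of smallest p were called for probe set 4999666 of Nrcam, a neuronal cell adhesion gene, at -2.62 relative to the rest of its gene (standard error 0.22, adjusted p = 9.05e-20), and probe set 4799673 of Rab27b, a GTPase of vesicle secretion, at -2.53 (adjusted p = 1.23e-08). The Nrcam probe set read 7.66 ± 0.90 (SD, n = 3) in control and 4.94 ± 0.41 (SD, n = 3) in knockdown arrays, and the change of the whole gene was -0.11. In knockdown arrays this probe set and those of Rab27b (4.07), Nbr1 (5.23) and Tbck (5.04) read below the filter value of 5.73, as did that of Nell2 in control arrays (5.60), so the sizes of these differences are uncertain. Relative falls were also called in the presynaptic scaffold gene Erc2, at -1.08, and in Nbr1, Snx30, Herc2 and Tbck. Relative rises were called in Cacna1d, a calcium channel gene, at 1.65 (adjusted p = 0.000175), in Nell2, at 0.89, and in Celf1 itself, where probe set 4717967 stood 1.86 above the rest of the gene. Without control replicate 2 the calls of Herc2 (adjusted p = 0.0674), Tbck (0.0858) and Celf1 (0.0629) ended, and without Cugbp1 shRNA replicate 3 those of Tbck (0.0629) and of Nbr1 (0.180), whose value went from -1.85 to -0.86.

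In all, 201 of 244785 probe sets in 176 genes passed, 108 relatively higher and 93 lower, and 146 genes passed the Simes test, of which 51 were also called as genes. A fit with the replicate block passed 5796 probe sets, including all 201, and 3232 genes. With this block 88.4% of diffSplice calls were false in the independent simulation and 71.6% in the paired one. No list held more exon usage genes than others by Fisher's exact test (smallest adjusted p = 0.883 over 23 lists). With 146 such genes among 16532, few were expected in any list, so this test had little power. Each list held 0 or 1. The 26 transcripts reported as regulated by CELF1 held 0, and the 1 in the CELF family was Celf1 itself. The diffSplice test uses 1 variance per gene. A splicing index with a variance per probe set, chosen after seeing the data, gave like sizes (Nrcam -2.61, Rab27b -2.51, Erc2 -1.08 and Cacna1d 1.64) and called 0 without the block (limma, 10475 at an unadjusted p under 0.05) and with it (27761). Without the block 88.7% of diffSplice calls were false in the independent simulation and 15.6% in the paired one, where variances were also moderated. For these arrays the shares of the independent simulation may be too high and those of the paired one too low. Of simulated changes of 1 the index recovered 0% and 10% without the block, in the independent and the paired simulation, and 0% and 47% with it, and of changes of 2 it recovered 60% and 72%, and 0% and 98%. The balance of directions moved with single arrays: 700 were relatively higher and 185 lower without control replicate 1, 22 and 14 without control replicate 2, and 177 and 355 without control replicate 3. Without Cugbp1 shRNA replicates 1, 2 and 3 they were 75 and 118, 36 and 53, and 57 and 25.

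Single probe sets gave no calls. Of 597778 probe sets tested with limma 0 passed, 35379 had an unadjusted p under 0.05, and the smallest adjusted p was 0.417. The count was also 0 with the replicate block, 188 with trend and robust variances, 5789 with array weights and 6244 with a random replicate block.

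The arrays correlated with each other at 0.953 to 0.981 across all probe sets. The first principal component of gene values, with 43.9% of the variance, separated replicate 1 of both groups from replicates 2 and 3, and the second, with 37.0%, separated the groups. The log2 changes of single replicate pairs correlated across genes at 0.69 (replicates 1 and 2), 0.61 (1 and 3) and 0.75 (2 and 3), where genes are not independent replicates. In replicates 2 and 3 alone, a subset chosen after seeing the data, limma called 678 genes, 256 higher and 422 lower. Of these, 672 had the same sign in replicate 1, which was 99.1% against 71.6% for all genes, and 442 were among the 652.

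**Figure D4:**
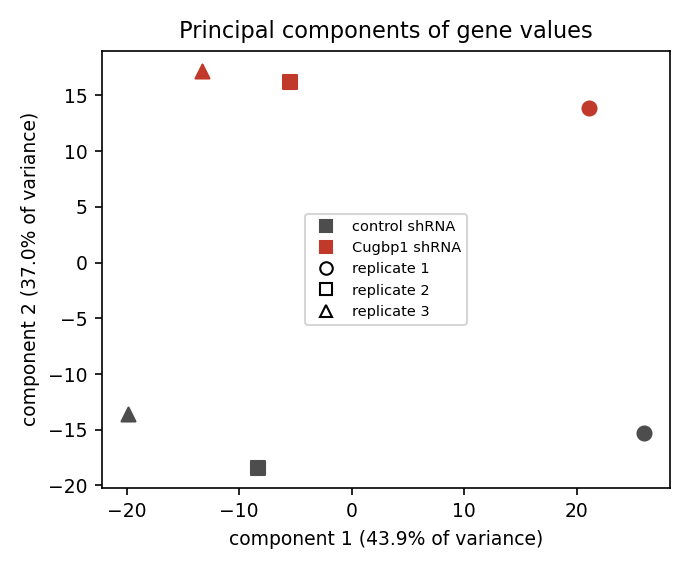
Positions of the 6 arrays on the first 2 principal components of gene values, in component units, with control shRNA in grey, Cugbp1 shRNA in red and a symbol per replicate number. Component 1 holds 43.9% of the variance and sets replicate 1 apart, and component 2 holds 37.0% and sets the groups apart.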

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

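In all 28 alternative settings were run, and the 9 tests with replicate pairs alone or a splicing index were chosen after seeing the data. The cause of a change was not tested, except that leaving out arrays and pairs of replicates use fewer arrays by construction. Against 652 genes called (72.2% lower), 3834 were called with the replicate block (59.7% lower), 4578 with a random block (58.5% lower), 2539 with a block for the label form (61.6% lower), 4226 with array weights (59.2% lower), 1091 with trend and robust variances, 1058 with the filter at the 75th percentile, 1351 at an adjusted p under 0.10 and 261 with at least 1 probe set per gene. Quantile normalization gave 660 (70.2% lower) and median centring 542 (71.6% lower). Leaving out single arrays gave 0 to 271. Replicates 1 and 2 alone gave 0 genes, or 1368 with a replicate block, replicates 1 and 3 gave 0 in both fits, and replicates 2 and 3 gave 678 (62.2% lower), or 2186 (57.8% lower) with a block. All 43 named genes called besides Celf1 kept their direction in every setting that measured them. All 652 called genes, Celf1 among them, had groups that did not overlap on the arrays. Leaving out arrays could therefore hardly turn a direction, so the kept directions are no separate evidence. Over all 6 arrays the 43 genes also kept their call with each block, array weights and trend. Of them 42 kept it with quantile normalization, 40 with centring, 37 with no filter, 38 with means and 27 with at least 1 probe set per gene. In replicates 2 and 3 alone 38 kept it, without control replicate 1 25, without Cugbp1 shRNA replicate 1 1, and none without any of the other 4 arrays or in replicates 1 and 2 or 1 and 3 without a block. With a replicate block 42 kept it in replicates 2 and 3, 41 in 1 and 2, and 0 in 1 and 3. Over all single genes, exon usage probe sets and lists named, 1762 values kept direction and side of the threshold, 231 newly passed, 418 no longer passed and 25 reversed.

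Celf1 kept its direction in each setting, between -1.43 and -1.14. It did not pass with replicates 1 and 2 (-1.30, adjusted p = 0.208) or 1 and 3 (-1.32, adjusted p = 0.474), nor with 1 and 3 and a block (adjusted p = 0.0763). Over all its alternatives the adjusted p ran from 7.99e-05 to 0.474. Without single arrays it was -1.43 to -1.32. Probe set calls rose from 0 to 6244 with a random replicate block, 188 with trend and robust variances and 5789 with array weights. Exon usage calls went from 201 to 5796 with the replicate block, 1712 with a block for the label form, 332 with no filter, 1764 with array weights and 302 at an adjusted p under 0.10. They were 566 in replicates 2 and 3, 116 in 1 and 2, and 6 in 1 and 3, and 36 to 885 without single arrays. The splicing index called 0 in each of its 3 forms (smallest adjusted p = 1, 0.278 and 0.132, with 10475, 27761 and 29308 at an unadjusted p under 0.05 in limma). The number of lists past the camera threshold went from 5 to 0 with an estimated correlation, to 6 with the replicate block, and to 5 to 8 without single arrays.

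The values that reversed did not pass with all 6 arrays. Celf4 was at 0.0019 with means of probe sets. Without single arrays Celf3 ran from -0.27 to 0.045 and Tardbp from -0.22 to 0.080. The median log2 change without single arrays ran from -0.036 to 0.079 for voltage-gated channels, -0.029 to 0.062 for inflammatory genes, -0.014 to 0.053 for other splicing regulators, -0.078 to -0.0055 for guidance genes, -0.12 to 0.19 for oligodendrocyte lineage, -0.12 to -0.011 for microglia, -0.14 to 0.045 for endothelial and mural, -0.10 to 0.067 for fibroblast and -0.082 to -0.016 for astrocyte markers, where camera's direction turned in at least 1 case. Of these the oligodendrocyte lineage list passed without control replicate 1 (0.19, adjusted p = 0.0182, within 0.0182 to 0.994 without single arrays) at the preset correlation. It turned too for astrocyte markers in replicates 1 and 2 (median -0.0070) and for inflammatory genes in 1 and 3 (median -0.076). The filter at 5.73 is the median of all probe sets, so signal close to it limits what small changes there can show.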

Other observations

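The tests chosen after the result was seen were those of lagging probe sets within genes that moved and of other cell types beside the proliferation list, with and without single arrays, and the sialyltransferase and motile cilia lists were written after some of their members had been seen.

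Genes that attach sialic acid to glycans moved in both directions. Of 20 sialyltransferases 5 were called, with St6gal1 rising by 1.08 and 4 falling: St6gal2 by 1.12, St3gal1 by 1.03, St6galnac5 by 0.97 and St8sia2, a polysialyltransferase, by 0.79. The share called was above that of other genes by Fisher's exact test (p = 0.000889), but 4 members had been seen among the called genes before the list was written, so this p is not independent evidence. The replicate block gave 4 that rose and 7 that fell, where it called 3834 of all 16532 genes.

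A hypothesis from the rises of Rsph4a, Cfap300 and Erich6 was that motile cilia genes rose as a set. Of 60 other motile cilia genes 2 rose, Cfap206 by 0.79 and Wdr78 by 0.65. With the replicate block, which called 3834 of all 16532 genes, 8 rose and 5 fell. The median of -0.0078 stood at percentile 85.59 of 10000 random lists matched on level, under the value of 0.013 at their upper limit that a set-wide rise required. A test of whether a few genes made the shift, the list without its 5 highest members at percentile 56.57, decided nothing, since the list showed no shift.

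Oxidative phosphorylation genes were higher by a median of 0.17. Signal level and number of probe sets did not account for it, since this median stood at percentile 99.98 of 10000 random lists matched on both. Normalization stays open, since quantile normalization and median centring moved gene values too little to test it (95% of genes by at most 0.018, and the smaller of the list medians was 0.171). A biological effect of the knockdown stays open as a hypothesis, as does correlation between the genes, since the list's adjusted p was 0.732 with an estimated correlation.

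Proliferation genes were higher by a median of 0.23, though the list did not pass with an estimated correlation (adjusted p = 0.878). The 75th percentile of 48 astrocyte, oligodendrocyte lineage and fibroblast markers was 0.083, below the proliferation median, which argued against a lower share of neurons. This rested on single arrays, since the 2 values were 0.167 and 0.165 without control replicate 1 and 0.0860 and 0.0864 without Cugbp1 shRNA replicate 2. Pan-neuronal and glutamatergic markers leaned lower, with 14 of 20 and 17 of 21 genes at a lower mean, where the median log2 change of all genes was -0.015. The GABAergic list had no settled direction, with 9 of 16 genes lower and a mean log2 change of 0.039. None of these 3 lists passed camera (adjusted p = 0.401, 0.241 and 0.557). Microglia and endothelial and mural markers, not among the 48, were also mostly lower (13 of 16 and 9 of 13). A lower share of neurons and a change among dividing cells alone therefore both stay open.

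Exon usage calls could come from dim probe sets that follow their gene less. As a cause of all calls this was argued against by a bound set before the result was seen, since 35.3% of the calls, under 50%, lay in genes with an absolute log2 change of at least 0.5, although such genes held 5.38% of the probe sets tested, which goes with lagging. Within those 71 calls 81.7% moved less than or against their gene (exact binomial p = 6.27e-08), a test split off after the 35.3% was seen. That p counts several probe sets of 1 gene, such as those of Celf1, as independent. The test used direction and not level, so it cannot tell whether dim probe sets were the cause. Lagging calls included bright probe sets, such as 4586056 of Vopp1 at 12.78 in control arrays, and dim ones, such as 5311247 of Dach2 at 6.33. The 75th percentile of level over all probe sets of the table was 7.46, and 183093 of the probe sets tested lay above it and 61692 below. The probe sets called made up 0.0415% of those tested above this level and 0.203% of those below. For the lagging and the remaining calls a splicing change and noise of single probe sets stay open.

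The 6 arrays have 10 splits into 3 and 3, too few for a share under 0.05. The real split called 652 genes and the highest other 0, and 1 split in 10 gave as many. For exon usage the real split gave 201 calls and the highest other 4211, and 6 of 10 gave as many. The 3 other splits that part all 3 pairs gave 0 to 1, while splits that part 1 pair keep 2 same-numbered pairs whole and gave 61 to 4211, which points to a structure of the samples by replicate number. The real split gave 5796 with the replicate block. For gene lists the real split gave 5 and the highest other 10, with 4 of 10 as many, 1 of them a split that parts all pairs with 6. Probe sets gave 0 in all 10 splits.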
